A study of Homo sapiens with 3 samples.

How the data were processed

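Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 acetylated at lysine 4 (H3K4Ac) in FaDu cells, an established line from a squamous cell carcinoma of the pharynx. The series holds 3 samples: 1 H3K4Ac library from cells kept at about 20% oxygen (normoxia), 1 H3K4Ac library from cells kept at 1% oxygen for 18 hours (hypoxia), and 1 input library. Peak lists of the normoxia and the hypoxia library were analysed. No processed values of the input library were analysed here.

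Per the submitters' processing notes, Bowtie2 2.0.4, MACS 1.4.2 and the genome build hg19 were used. Per the file headers, the authors called peaks with MACS in each library separately, against the same control library for both conditions. Whether this control is the input sample of the series, and from which oxygen condition it came, is not given in the sources used here. The header settings were a read length of 101 bp, an average fragment length of 200 bp, an effective genome size of 2700000000 bp, a p-value cutoff of 1e-05, an enrichment factor of 12 and local bias detection. The name of the hypoxia library in its header includes the word "combined"; what was combined is not given in the sources used here. The deposited unit is other than a count or a signal: each line gives a chromosome, a start and an end. The 3 columns hold no peak height, score, fold enrichment or p-value, so a peak is either present or absent. Read depth is unknown, and a longer list or wider peaks can come from a deeper or better enriched library.

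Identical lines were counted once. This left 31155 normoxia peaks from 35153 lines and 31695 hypoxia peaks from 31695 lines. No peak overlapped another of its own list. Positions are printed 1-based on hg19, with BED starts raised by 1.

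A peak was called shared when at least 1 bp was covered by a peak of the other list, and normoxia-only or hypoxia-only otherwise (bedtools 2.31.1; Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1). Chance overlap was described by 100 random placements of each list over the span of its own chromosomes, and by 100 sets of random shifts of 20 to 100 kb in either direction. Shared and condition-only peaks were counted in 1-Mb bins by peak midpoint. Bins were grouped by the number of shared normoxia peaks they held; bins with no peak of either list did not enter. Runs were consecutive peaks of the same class along a chromosome. They were compared, also after joining of neighbouring peaks and under 2 other alternatives, with 100 permutations of the class labels within each chromosome and 100 within windows of 50 consecutive peaks. Condition-only peaks were also counted with no peak of the other list within 1000 or 5000 bp. Counts by chromosome and bin cover chromosomes 1 to 22 and X. The code of the overlap functions was checked on a simulated list made from the 31155 normoxia peaks. Edges of kept peaks were moved by at most 100 bp, and added peaks were put in the middle of wide gaps. In it 100% of 24997 kept peaks were found shared and 100% of 2000 added peaks were found to be new. These settings fix both results in advance, so they check the code only. Of 6158 dropped peaks, 1.45% were called shared because a neighbour reached them.

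There was 1 library per condition, so no difference has a replicate check and no p-value is given. Intervals on shares are 95% Wilson intervals. They cover counting error only and treat peaks as independent. The interval of a difference between 2 shares is a normal approximation.

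Choices fixed before the data were examined included the overlap rule, the random placements over whole chromosomes, the counts by chromosome and the comparison of genes by promoter peaks. That comparison, the fixed gene lists and the shares of peaks at promoters need gene positions on hg19; the gene table at hand is on GRCh38, coordinates were not converted between builds, and these parts were not analysed here. Planned filters on peak score could not be run without scores. The rule for named regions was planned by score: the 10 highest-scoring condition-only peaks of each list with no peak of the other list within 5000 bp. Width took the place of score, a change made after the columns were seen. The shifts of 20 to 100 kb, the density bins, the runs, the densely covered bins (at least 25% of 1 Mb inside peaks in either list, which all reached in normoxia) and the width analyses were chosen after the data were seen. Alternatives covered the overlap rule, list length, width, joining of neighbouring peaks, repeated lines, bin size and densely covered bins.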

Results

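The comparison asked where the genome of a head and neck squamous carcinoma line carried H3K4Ac at atmospheric oxygen and after 18 hours at 1% oxygen. H3K4Ac is a histone acetylation found mainly at active promoters and enhancers. There was 1 library per condition, so every difference described is between 2 libraries. The normoxia list held 31155 peaks that covered 100.7 Mb, and the hypoxia list held 31695 peaks that covered 83.9 Mb. Read depth is unknown.

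Most H3K4Ac sites were found in both conditions. Of the normoxia peaks, 24407 (78.3%, 95% interval 77.9 to 78.8%) were overlapped by a hypoxia peak, and of the hypoxia peaks 26300 (83.0%, 82.6 to 83.4%) were overlapped by a normoxia peak. By chance placement on the same chromosomes, 6.55% of normoxia and 6.74% of hypoxia peaks overlapped the other list, with a highest value of 7.01% over the placements. Random shifts of 20 to 100 kb, which keep each peak in its neighbourhood, gave 15.0% and 15.6%. The covered stretches had 70.4 Mb in common, which was 69.9% of the normoxia and 84.0% of the hypoxia covered length.

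A smaller set of sites was called in one condition only: 6748 normoxia-only and 5395 hypoxia-only peaks. With only peaks of at least 2000 bp kept in both lists the counts were 6172 and 2076, so their ratio depended on this filter, which keeps more normoxia peaks. Some of these lay beside a peak of the other list. With no peak of the other list within 5000 bp, 4202 normoxia and 3679 hypoxia peaks remained. Condition-only peaks were narrower than shared ones, with medians of 1493 against 2691 bp in normoxia and 1224 against 2178 bp in hypoxia. With each list split by width into 10 groups of about equal number, the share of normoxia peaks that were shared was 45.9% (44.2 to 47.7%) in the narrowest group (493 to 1205 bp) and 97.3% in the widest. In hypoxia the same shares were 55.0% (399 to 974 bp) and 98.9%. Isolated condition-only peaks of at least 2000 bp numbered 1111 in normoxia and 762 in hypoxia, out of 19209 and 15578 peaks of that width.

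**Figure D1:**
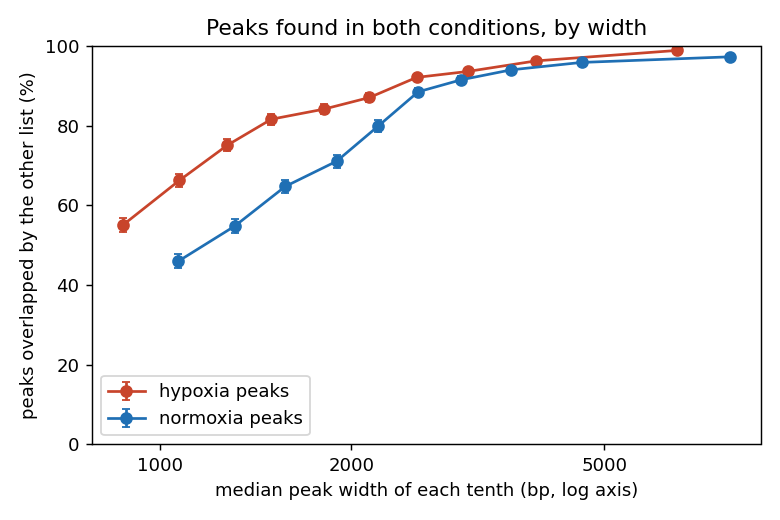
Share of peaks overlapped by the other list (vertical axis, %) against the median peak width of each of 10 width groups of a list (horizontal axis, bp, log scale), with 95% Wilson intervals, for normoxia (blue) and hypoxia (red). Sharing rose from 45.9% to 97.3% of normoxia peaks and from 55.0% to 98.9% of hypoxia peaks between the narrowest and the widest group. Chance overlap, which also rises with width, was not computed by group.

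Peaks at shared sites were narrower in hypoxia. Over 19583 sites where 1 normoxia peak met 1 hypoxia peak, the median width was 2619 bp in normoxia and 2226 bp in hypoxia. The hypoxia peak was narrower at 14505 of them (74.1%, 73.5 to 74.7%) and wider at 5065. The median log2 ratio of hypoxia to normoxia width was -0.21, with quartiles of -0.50 and 0.01. Both edges lay further in, by a median of 142 bp on the left and 141 bp on the right. Normoxia peaks more often spanned several peaks of the other list: 9.02% of them overlapped 2 or more hypoxia peaks, against 3.93% in the other direction. The longest domains followed the same order, with 926 peaks of at least 10000 bp in normoxia and 525 in hypoxia. Of the 525 hypoxia domains, 458 overlapped a normoxia domain of that length and 521 overlapped a normoxia peak of any width. In the other direction, 428 of the 926 normoxia domains overlapped a hypoxia domain of that length and 907 a hypoxia peak of any width.

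Sites called in one condition only were placed differently along the genome in normoxia and hypoxia. In 1-Mb bins with at most 5 shared peaks, 1419 condition-only peaks were hypoxia-only and 1052 normoxia-only, a hypoxia-only share of 57.4% (55.5 to 59.4%). In bins with over 20 shared peaks the counts were 1136 and 2419, a share of 32.0% (30.4 to 33.5%). The difference between sparse and dense bins was 25.5 points, with a 95% interval of 23.0 to 28.0 points. Counts of condition-only peaks varied between bins more than independent counts would. The variance over the mean was 1.71 (hypoxia-only) and 1.49 (normoxia-only) in sparse bins, and 1.69 and 3.10 in dense bins. The interval treats peaks as independent, so it is likely too narrow. Normoxia-only peaks per bin went from 0.551 in bins with 1 to 2 shared peaks to 8.14 in bins with over 20, and hypoxia-only peaks from 0.906 to 3.82. Bins with 0 shared peaks, which entered only where they held a condition-only peak, had 0.677 and 0.995, with a hypoxia-only share of 59.5% (54.1 to 64.7%). Hypoxia-only peaks also lay further from shared sites. Their median distance to the nearest shared peak of their own list was 19.0 kb, against 11.2 kb for normoxia-only peaks, and 1660 of 5395 (95% interval 29.6 to 32.0%) against 1418 of 6748 (20.1 to 22.0%) lay more than 50 kb away.

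**Figure D2:**
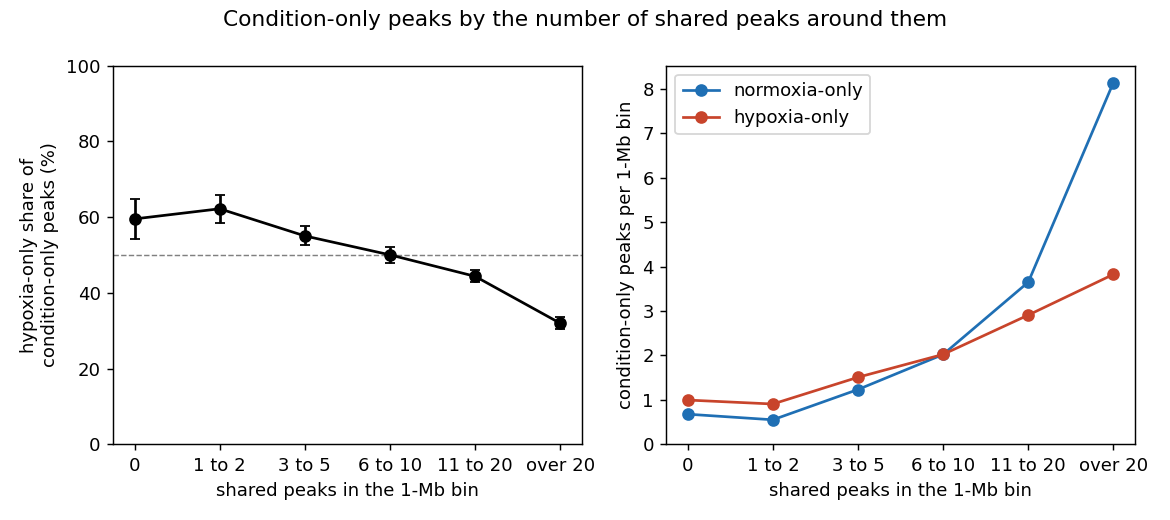
Left, hypoxia-only share of condition-only peaks (%, with 95% Wilson intervals and a dashed line at 50%) against the number of shared peaks in the 1-Mb bin; right, mean number of normoxia-only (blue) and hypoxia-only (red) peaks per bin. The hypoxia-only share was 59.5% in bins with 0 shared peaks, 62.2% in bins with 1 to 2 and 32.0% in bins with over 20.

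The same order was seen between chromosomes. Chromosomes 17, 19 and 22, which are rich in genes, carried 22.6, 21.9 and 24.6 normoxia peaks per Mb, while the gene-poor chromosomes 4, 13 and 18 carried 5.07, 6.11 and 5.01. On chromosome 22 the ratio of hypoxia-only to normoxia-only peaks was 0.407, with 248 normoxia-only peaks, and chromosome 17 had 208 and 450, a ratio of 0.462. Chromosome 18 had 125 and 93, a ratio of 1.34, and chromosome 4 had 259 and 206, a ratio of 1.26, while chromosome 13 had 118 and 121, a ratio of 0.975. Not every chromosome followed this order. Chromosome X, with the fewest shared peaks per Mb (2.67), had a ratio of only 1.04. Chromosome 21, with 6.12 shared peaks per Mb, had a ratio of 0.621. Hypoxia-only peaks outnumbered normoxia-only peaks on 6 of 23 chromosomes (2, 4, 5, 8, 18 and X). The hypoxia-only share of condition-only peaks fell with shared peaks per Mb, with Pearson's r of -0.83 and Spearman's rho of -0.75 across the 23 chromosomes, which are not independent replicates. Without chromosomes 19 and 22, the 2 farthest from the median density, r was -0.77 and rho -0.67. Under the processing alternatives run on it, rho over all 23 chromosomes lay between -0.77 and -0.53. It was weakest with peaks of at least 2000 bp in both lists. In total peak number, the share of the list on each chromosome differed little: the ratio of the hypoxia to the normoxia share was lowest on chromosome 21, at 0.889, and highest on chromosome 18, which carried 5.60 hypoxia and 5.01 normoxia peaks per Mb.

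**Figure D3:**
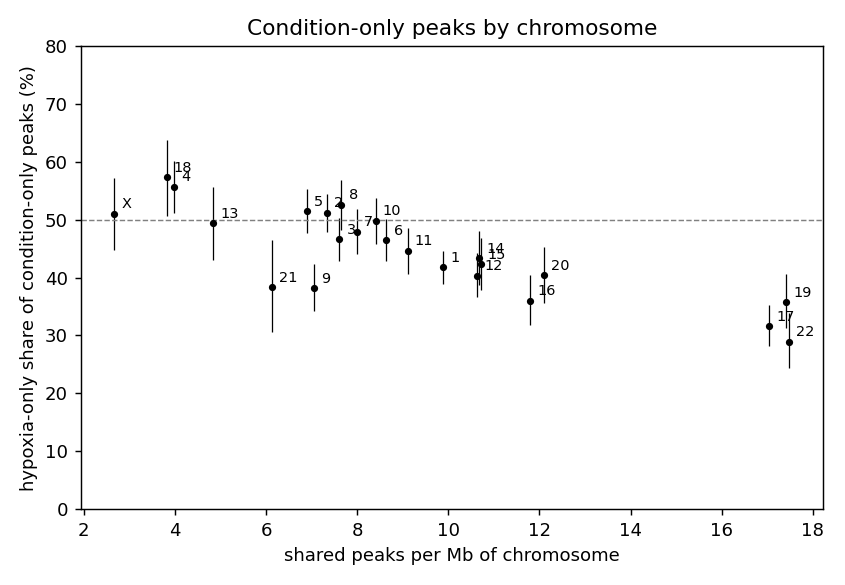
Hypoxia-only share of condition-only peaks (vertical axis, %, with 95% Wilson intervals and a dashed line at 50%) against shared peaks per Mb (horizontal axis) for chromosomes 1 to 22 and X, each point labelled with its chromosome. The share was 28.9% on chromosome 22 and 57.3% on chromosome 18.

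Condition-only peaks of the same class stood next to each other in runs of at least 3 more often than under permuted labels. A run counts the order of peaks only, whatever the distance between them. There were 261 runs of at least 3 consecutive hypoxia-only peaks with no shared or normoxia-only peak between them, against a mean of 110 and a highest value of 132 over permuted labels within chromosomes. Permutation within windows of 50 peaks gave a mean of 138 and a highest value of 169. Normoxia-only runs numbered 270, against means of 192 and 212 and highest values of 227 and 249. Runs of at least 6 peaks numbered 14 in hypoxia, where the permutations within chromosomes gave at most 3 and those within windows at most 6. In normoxia there were 2 such runs, where permutations gave up to 5 and 7. Part of the runs came from peaks that lay close together. With peaks within 1000 bp of each other joined in each list, runs of at least 3 numbered 179 in hypoxia and 171 in normoxia, against highest values of 131 and 169 in the permutations within windows. Runs of at least 6 hypoxia-only peaks then numbered 3, where permutations within chromosomes gave up to 2 and those within windows up to 5. With peaks of at least 2000 bp in both lists, runs of at least 3 numbered 62 in hypoxia and 461 in normoxia. Runs of at least 6 numbered 2 and 21, so which list held more runs of either length depended on the filter. That filter counts a wide peak as condition-only where the other list holds only a narrower one. The longest run held 12 hypoxia-only peaks on chromosome 2 from 12457425 to 13823024, which covered 16.95 kb within 1366 kb. Runs of 7 hypoxia-only peaks lay on chromosome 10 from 4718155 to 4771422, chromosome 11 from 121499987 to 122008831 and chromosome 12 from 76083619 to 76258298. The chromosome 10 run held 17.6 kb of peaks within 53.3 kb. A compact run of 6 hypoxia-only peaks covered 12.2 kb within 24.6 kb on chromosome 20 from 52790259 to 52814903. The 2 long normoxia-only runs were 7 peaks on chromosome 12 from 52690105 to 52719522 and 6 peaks on chromosome 4 from 141445086 to 142298305. Which genes lie at these positions was not analysed here.

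Over 1-Mb bins, hypoxia peaks covered less than normoxia peaks in 1830 of 2619 bins and more in 789. The bin with the largest excess in hypoxia was 4 to 5 Mb on chromosome 10, which holds the run of 7 hypoxia-only peaks, with 4.94% covered against 1.49% in normoxia. On chromosome 7, 157 to 158 Mb was covered to 8.25% in hypoxia and 5.21% in normoxia. On chromosome 9, 18 to 19 Mb was covered to 2.30% and 0.448%. On chromosome 11, 102 to 103 Mb was covered to 24.6% and 22.7%. The largest deficit in hypoxia was 91 to 92 Mb on chromosome 14, with 17.0% covered against 42.2% in normoxia. Next came 46 to 47 Mb on chromosome 22, with 55.1% against 75.4%, and 43 to 44 Mb on that chromosome, with 27.7% against 46.1%. This ranking is by percentage points, so a large deficit is possible only where much of a bin is covered. By ratio of hypoxia to normoxia covered length, the 3 bins had 0.404, 0.731 and 0.601. The median ratio of the 26 densely covered bins was 0.676, so 46 to 47 Mb on chromosome 22 lay above it.

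Very long covered stretches stood out in both conditions. In 26 bins at least 25% of the sequence lay inside normoxia peaks, and 9 of these also reached that share in hypoxia. The ratio of hypoxia to normoxia covered length over the whole genome was 0.833. The most covered bin was 69 to 70 Mb on chromosome 11, with 85.5% in normoxia and 68.8% in hypoxia, made up of 10 and 15 peaks. The widest normoxia peak ran from 69965268 to 70191289 on that chromosome (226 kb). The widest hypoxia peak ran from 70879247 to 71092964 (214 kb), where a normoxia peak ran from 70879116 to 71093053. Between them, a stretch of 670 kb from 70191290 to 70861305 held no peak of either list. The bin at 128 to 129 Mb on chromosome 8 was covered to 46.8% in normoxia and 32.1% in hypoxia.

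**Figure D4:**
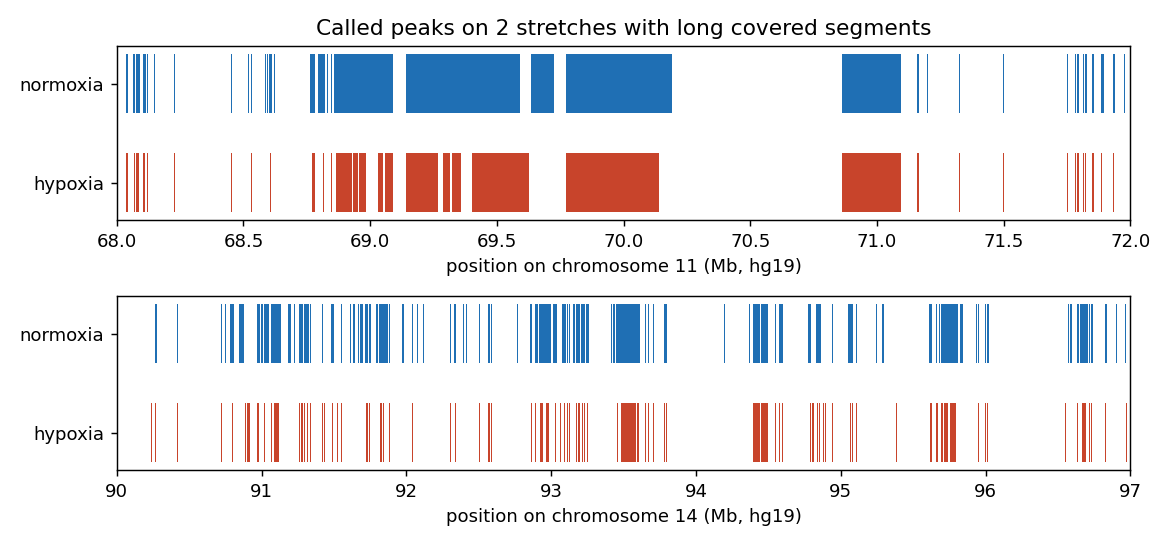
Called peaks in normoxia (blue) and hypoxia (red), drawn to scale by position (Mb, hg19) on chromosome 11 from 68 to 72 Mb and chromosome 14 from 90 to 97 Mb; each bar is 1 peak. Peaks covered 85.5% of 69 to 70 Mb on chromosome 11 in normoxia and 68.8% in hypoxia, while on the chromosome 14 stretch they covered 1766 kb and 986 kb.

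The widest condition-only peaks with no peak of the other list within 5000 bp lay mostly on chromosome 14 in normoxia and were more spread in hypoxia. Of the 10 in normoxia (10.9 to 90.7 kb), 8 lay on chromosome 14, 1 on chromosome 11 and 1 on chromosome 15. The widest was on chromosome 11 from 69634179 to 69724852, inside the long covered stretch. Just before it lay the chromosome 11 peak of the hypoxia list, from 69620460 to 69628321 (7.86 kb). No other peak lay between them, so both belong to the same covered stretch and are not separate places. A further hypoxia peak in this stretch, from 69589997 to 69620336, was overlapped by no normoxia peak. It did not enter the 10, because a normoxia peak that ended at 69589817 lay within 5000 bp. The next widest in normoxia were on chromosome 14 from 91032881 to 91051735 (18.9 kb), from 96582369 to 96599060 (16.7 kb) and from 93152088 to 93167816 (15.7 kb). On chromosome 15 the peak ran from 100772196 to 100784322 (12.1 kb). Of the 10 in hypoxia (6.42 to 15.7 kb), 4 lay on chromosome 14, 3 on chromosome 9 and 1 each on chromosomes 11, 15 and 22. The widest were on chromosome 14 from 90901432 to 90917175 (15.7 kb), on chromosome 15 from 102151881 to 102164061 (12.2 kb) and on chromosome 14 from 94805328 to 94815908 (10.6 kb). Directly beside the last of these lay another of the 10, from 94798487 to 94804908 (6.42 kb). The chromosome 9 peaks ran from 16362976 to 16371163 (8.19 kb), from 18456207 to 18462763 (6.56 kb) and from 4919670 to 4926119 (6.45 kb). The chromosome 22 peak ran from 47500673 to 47507388 (6.72 kb). From 90 to 97 Mb on chromosome 14, 128 normoxia peaks covered 1766 kb and 144 hypoxia peaks covered 986 kb, so both lists held many peaks there, of a median 9482 and 5010 bp.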

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

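All tests in this part were chosen after the results were seen. In the normoxia list, 3570 peaks stood on 2 or more identical lines, and 1 peak stood on 11; in the hypoxia list no line was repeated. These repeats lie outside the measurement compared in the report, which counted each peak once. Repeated peaks were shared with hypoxia more often than peaks on 1 line: 86.7% (95% interval 85.6 to 87.8%) against 77.3%. The share was 86.2% for 2 lines, 91.1% for 3 and 94.8% for more than 3. Single-line peaks of the same widths as the repeated peaks were shared at 79.8%.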

How the results depend on the processing

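No signed value changed sign under the 11 alternatives, of which 2 were planned and 9 were chosen after seeing the data, but the order of the lists by number of runs did change. Shares of normoxia and hypoxia peaks shared, 78.3% and 83.0% as reported, were 76.9% and 81.4% when at least 50% of either peak had to be covered, 81.5% and 85.4% when peaks within 1000 bp counted as shared, 77.9% and 83.6% with the same number of widest peaks from each list, and 76.3% and 80.0% with 50% of that number. With that smaller number, normoxia-only peaks numbered 3684 and hypoxia-only peaks 3118, since fewer peaks entered. With peaks of at least 2000 bp in both lists the shares were 67.9% and 86.7%, and hypoxia-only peaks numbered 2076. That filter keeps more normoxia than hypoxia peaks, and counts a wide peak as condition-only where the other list holds only a narrower one. Joining peaks within 1000 bp of each other gave 80.0% of normoxia peaks shared, and counting repeated lines as separate peaks gave 79.4%. The difference in hypoxia-only share between sparse and dense bins, 25.5 points, was 31.3 with the smaller number of widest peaks and 18.2 with peaks of at least 2000 bp in both lists; the cause was not tested. It stayed within its interval under the other alternatives run on it. Runs of at least 3 peaks, 270 in normoxia and 261 in hypoxia as reported, numbered 232 and 242 when peaks within 1000 bp counted as shared, 461 in normoxia and 62 in hypoxia with peaks of at least 2000 bp, 154 and 148 with the smaller number of widest peaks, and 171 and 179 with neighbours joined. With peaks of at least 2000 bp, permuted labels within windows gave at most 419 and 38. They gave at most 145 and 113 with the smaller number of widest peaks, and 169 and 131 with neighbours joined. The margin for normoxia-only runs was thus small after joining. Labels were not permuted for the rule in which peaks within 1000 bp counted as shared. Runs of at least 6, 2 in normoxia and 14 in hypoxia as reported, numbered 1 and 3 after joining, 3 and 7 with the smaller number of widest peaks, and 21 and 2 with peaks of at least 2000 bp; permuted labels within windows gave at most 4 and 5, 6 and 3, and 21 and 2. Score filters, promoter widths and gene lists were not run, because no scores and no hg19 annotation were used. No paired analysis was possible because each condition had 1 library. With depth unknown, a site called in one list only can lie just under the threshold in the other.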

Other observations

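All tests in this part were chosen after the results were seen. Further runs of 6 hypoxia-only peaks were found on chromosome 12 from 15305940 to 15694768, chromosome 8 from 10593110 to 11374884, chromosome 9 from 111207115 to 111315302 and chromosome 18 from 70393531 to 71231091. Runs of this length fell from 14 to 3 in number when peaks within 1000 bp were joined, where permutations gave up to 2 within chromosomes and up to 5 within windows. The chromosome 12 run lay in a bin, 15 to 16 Mb, that was covered to 4.17% in hypoxia and 2.41% in normoxia. Hypoxia peaks also covered more of 233 to 234 Mb on chromosome 1 (4.39% against 2.23%), of 54 to 55 Mb on chromosome 7 (4.65% against 2.53%) and of 111 to 112 Mb on chromosome 3 (7.66% against 5.66%).

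Hypoxia-only peaks took a larger share of condition-only peaks where few sites were shared, a difference of 25.5 points between sparse and dense bins. Splitting and edges of broad peaks do not explain it, because the difference was 25.3 points (22.3 to 28.2) with condition-only peaks over 5000 bp from any peak of the other list. The difference was not confined to narrow peaks: among condition-only peaks of at least 2000 bp it was 35.1 points (29.7 to 40.5). It was 18.2 points when narrower peaks were left out of both lists. Without scores, width does not tell whether a peak lay near the threshold, so peaks near the threshold stay open as an explanation. Even scatter of the hypoxia calls as the whole cause is excluded by 4.22 times as many hypoxia-only peaks per Mb (3.60 to 4.96) in bins with over 20 shared peaks as in bins with 1 to 2, but an evenly scattered part is not. What also stays open is a difference in depth, enrichment or GC bias between the 2 libraries, which cannot be examined without reads or a genome sequence. A redistribution of H3K4Ac in hypoxia towards sparsely marked regions stays open too, and needs replicate libraries.

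Long stretches of chromosome 11 from 69 to 70 Mb lay inside called peaks in both conditions. The long peaks may reflect a copy number gain that the control, whose oxygen condition is not given in the sources used here, did not remove, since this part of the chromosome arm is amplified in many head and neck squamous carcinomas, or a long acetylated domain present in both conditions. The overlap does not decide: 76.0% of the normoxia-covered length was also covered in hypoxia, but with 85.5% and 68.8% of the bin covered it could not have been under 63.5%. The explanations cannot be told apart from peak positions.

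Parts of chromosome 14 from 90 to 97 Mb were less covered in hypoxia. The deficit did not run evenly through the stretch. For example, the normoxia peak from 94394285 to 94443976 met a hypoxia peak of nearly the same extent, from 94393520 to 94441493. Among the 26 densely covered bins the 3 lowest ratios of hypoxia to normoxia covered length were all on this chromosome: 0.404 at 91 to 92 Mb, 0.523 at 95 to 96 Mb and 0.580 at 93 to 94 Mb. Over the whole stretch the ratio was 0.558. The bin at 91 to 92 Mb lay 3.23 SD below the mean of the 25 other densely covered bins (0.685 ± 0.0872 SD), but it was noticed as the largest deficit of 2619 bins, so this distance cannot exclude that peaks were narrower throughout the hypoxia list. A copy number difference between the cultures and a loss of H3K4Ac in hypoxia stay open too, untested.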
